A study of Mus musculus with 42 samples.

How the data were processed

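The series holds 42 samples of mouse splenic CD4 T cells. The samples analysed here were wild type (WT) or had a conditional knockout (cKO) of Trmt61a, the catalytic subunit of the tRNA m1A58 methyltransferase. The labels give the strain C57BL/6 and an age of 8 weeks for RNA-seq and m1A-seq only. For the RiboTag-seq samples the labels name a knockout of Trmt6, while the description of the series names Trmt61a. Naive CD4 T cells were isolated with a kit and stimulated with plate-bound anti-CD3 at 5 µg/ml and anti-CD28 at 2 µg/ml. RNA-seq covers 18 samples, m1A-seq 8, tRNA-seq 8 and RiboTag-seq 8, with 2 per group. RiboTag-seq and the WT RNA-seq samples of 18 h were not used here. The labels do not say whether the replicates of a group are separate animals, so tests between libraries measure the spread between these samples, which may be technical. Fisher's, binomial, sign-flip and correlation tests run over genes or isoacceptors and do not measure that spread. They treat genes or isoacceptors as independent, which they are not.

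For RNA-seq, the authors deposited 1 table per time point (0, 3, 6 and 48 h) that holds genes with an unadjusted p under 0.05. Its per-library values are a signal, namely gene read counts divided by 1 scaling factor per library, which the values bear out: in all 16 library columns 100% of the values above 0 were whole multiples of a common step (tolerance 0.01). The same deposited tables give a log2 fold change of cKO over WT, a p-value and an adjusted p-value, from a test the labels do not name. For tRNA-seq, the authors deposited read counts and reads scaled to the library total (RPM) on 242 reference sequences for each library, after treatment with AlkB, a demethylase that removes m1A before reverse transcription. For m1A-seq, the authors deposited 1 m1A level per genotype and tRNA isoacceptor in percent, the coverage as counts, the difference WT minus cKO as a score in percentage points, and the ratio of WT to cKO. How the percentages were called, and whether replicates were pooled, is not stated. The submitters' notes name mm10, Trim Galore 0.6.6, HISAT2 2.0.5, featureCounts 1.5.0-p3 and Bowtie2 2.4.1 without saying which assay each served.

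Groups followed the labels, and the comparisons, tests, gene lists and naming rule were fixed before the data were examined. Because the RNA-seq tables hold selected genes, a gene was called when the authors' adjusted p was under 0.05, with its direction from the authors' log2 fold change. The number of genes behind each adjustment, recovered from the p-values, was 24502 at 0 h, 15399 at 3 h, 16602 at 6 h and 9940 at 48 h. Listed genes that appeared to be set aside from the adjustment could not be called: 89 at 3 h, 27 at 6 h and 92 at 48 h. A gene is described as listed when it appears in a table. Means and SDs per group were computed from the scaled read counts. For each of 26 gene lists with at least 3 listed members, the split into higher and lower was compared with that of the other listed genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over 40 tests. Counts of list members are also given adjusted over the list alone. Listed members already had an unadjusted p under 0.05, so where most of a list is listed, passing this adjustment nearly follows from being listed. Such counts, as for interferon-stimulated genes at 6 h or cholesterol genes at 48 h, add no evidence of their own. Genes listed at 2 time points were compared in direction by an exact binomial test and by Fisher's exact test. Marker lists for pancreatic acinar cells and the submandibular gland were written after their genes had been seen in the tables.

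For tRNA-seq, reads were summed per anticodon, with initiator methionine apart, and fitted with edgeR 4.0.16 (quasi-likelihood, mean RPM of at least 10). Library sizes were the library totals, recovered from the deposited reads and RPM. All 8 libraries shared 1 estimate of the spread. The plan named limma on log2(RPM + 1) for this test; edgeR took its place once the files were seen to hold counts, and limma became an alternative. Each reference tRNA gene was tested in the same way. Because the tRNA share of the libraries shifted between times, the changes are also given with the tRNA reads as the library size and TMM factors, called the tRNA scale below. Group shares were compared by exact permutation tests (two-sided), which with 2 against 2 libraries cannot go below 0.333. For m1A, a sign-flip permutation test (two-sided, 100000 resamples) across isoacceptors describes the pair of columns, since no values per replicate were used.

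Named genes followed a rule: Trmt61a, Trmt6 and Myc; at each time the 8 called genes with the highest and the 8 with the lowest fold change, among those with a mean of at least 100, no overlap between the groups and an established symbol; up to 4 members per list with the lowest adjusted p; and up to 8 genes listed at 3 or more times. For tRNA it took the 5 isoacceptors at each end past the threshold plus initiator methionine, and for m1A the 5 largest and 5 smallest losses plus initiator methionine. Genes named outside the rule were chosen after their values were seen, and not all are marked so in place. Unmarked ones include Il5, Il13, Il21 and Tnf at 3 h, Il5 and Tigit at 6 h, and Hsp90b1, Lta and Bpifa2 at 48 h.

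The alternatives were an adjusted p under 0.01, an absolute log2 fold change of at least 1, a mean value of at least 10 or 100, protein-coding genes, limma 3.58.1, a replicate block, and each library left out in turn. Alternatives chosen after seeing the data were edgeR and DESeq2 1.42.0 on whole reads recovered from the scaled values, the 2 tissue lists and immunoglobulin genes left out, an adjusted p under 0.05 for the calls shared between times, a test of the listed share of each gene list, and for tRNA TMM, DESeq2 size factors, the DESeq2 test and a crossed replicate block. For tRNA the pseudocounts 0.1 and 10, no filter, a mean RPM of at least 100, no trend and median-centred values were also run. Tested on simulated data with the tRNA spread, edgeR recovered 100% of isoacceptor changes of 1.5-fold and 69.6% of such changes in single genes. With the RNA-seq spread at 3 h, 4-fold changes were recovered at 50.9% by edgeR, 63.2% by DESeq2 and 59.6% by limma, and 1.5-fold changes at 0%, 3.8% and 7.7%. On RNA-seq values, real or simulated, limma adjusted over the listed genes alone, and edgeR and DESeq2 over all genes behind the authors' adjustment. The limma counts are therefore not comparable with the others. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and R 4.3.3, and plots matplotlib 3.10.9.

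RNA-seq depth is unknown, because the tables hold listed genes only: these carry between 423873 and 674416 reads per library at 0 h and between 3380554 and 4482346 at 48 h. tRNA-seq libraries held between 67261117 and 92701839 reads. Reads carry no molecular identifiers, and at each time the difference between duplicate tRNA libraries far exceeded counting error, with a chi-square over its degrees of freedom between 819 and 2292, so counting intervals are not given.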

Results

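The series holds 42 samples of splenic CD4 T cells. Those analysed here came from WT mice and from mice with a conditional knockout (cKO) of Trmt61a, the catalytic subunit of the enzyme that places a methyl group on adenosine 58 of tRNAs (m1A58). Cells were taken at rest (0 h) or after stimulation through the T cell receptor and CD28. RNA-seq compared the genotypes at 0, 3, 6 and 48 h, with 2 libraries per genotype and time. m1A-seq, which reads the methylation level of each tRNA, compared them at 6 h. tRNA-seq followed WT cells at 0, 6, 18 and 48 h, with 2 libraries per time. Their totals, recovered from the RPM, lay between 67261117 and 92701839 reads. RNA-seq values below are scaled read counts as mean ± SD, and their depth is unknown because the tables hold only genes with an unadjusted p under 0.05. RiboTag-seq and the WT RNA-seq samples of 18 h were not analysed here.

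The comparison of m1A levels asks how far the knockout removed the modification. All 44 isoacceptors (tRNAs sharing an anticodon) had a lower m1A level in cKO than in WT cells, by a mean of 53.7 percentage points. The WT median was 90.8%, and 25 isoacceptors stood above 90%. In the cKO the median was 34.4%, with 39 isoacceptors below 50% and 17 below 30%. The losses were largest for Thr-AGT (93.8% in WT, 18.5% in cKO), Ile-AAT (85.7% and 13.6%), Arg-ACG (86.8% and 14.9%), Phe-GAA (92.3% and 21.6%) and Leu-TAA (86.9% and 16.4%). The smallest loss was in initiator methionine tRNA, the tRNA that starts protein synthesis, at 88.0% in WT and 85.9% in cKO, a difference of 2.07 points. Ala-AGC followed with 91.4% and 86.3%, then elongator Met-CAT with 94.4% and 67.4%. Ala-TGC stood at 88.6% in WT and 48.1% in cKO, and Pro-AGG at 75.4% and 34.9%. Across isoacceptors, which are not independent replicates, a sign-flip permutation test (two-sided) gave p = 1e-05, the smallest it can give. There is 1 value per genotype and no error, so no single isoacceptor was tested; the coverage ran from 727 reads for Ala-TGC to 28078 for Leu-TAG.

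**Figure D1:**
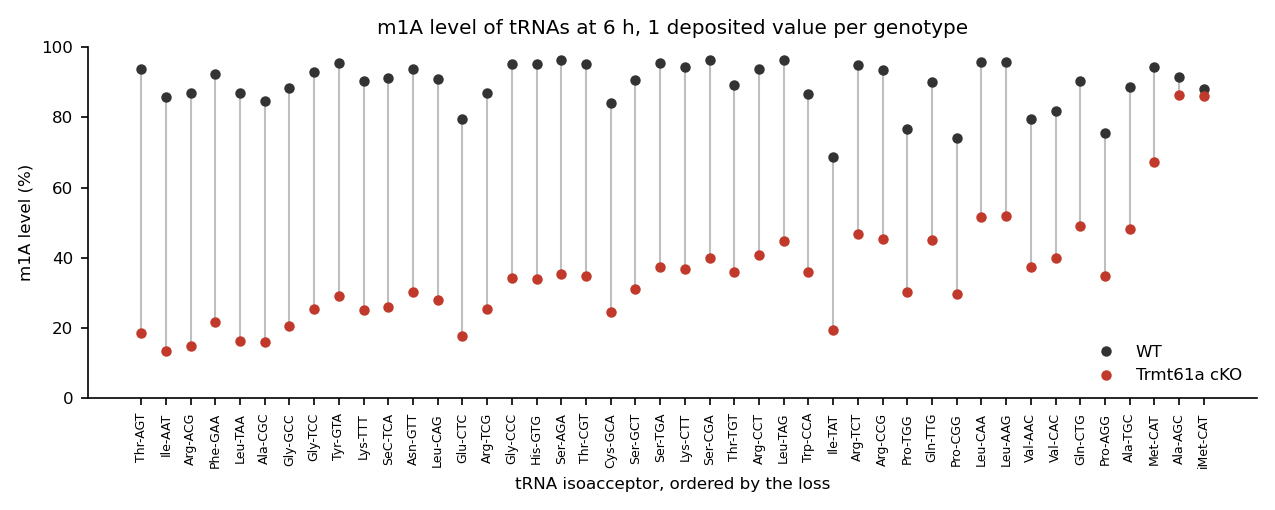
m1A level in percent (vertical axis) of 44 tRNA isoacceptors at 6 h in WT (dark points) and Trmt61a cKO cells (red points), ordered by the loss, with 1 value per genotype and no error. All cKO points lie below their WT points, from a gap of 75.3 points for Thr-AGT to 2.07 points for initiator methionine.

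The comparison at 0 h asks what the knockout changed before stimulation. Trmt61a (ENSMUSG00000060950, chromosome 12, 111678105 to 111683902 on mm10, plus strand) fell to 22.7 ± 0.186 (SD, n = 2) in the cKO from 289 ± 104 (SD, n = 2) in WT. In the authors' deposited table its log2 fold change was -3.67 (adjusted p = 1.16e-11). Trmt6, the partner subunit, was not listed at any of the 4 times. The table called 3 genes, all lower in the cKO: Trmt61a and a pair chosen here after their values were seen, Dcpp2 and Klk1b26. By limma 4 genes were called, 3 of them higher, and by edgeR on the recovered reads 6, 2 of them higher. DESeq2 on these reads called none as higher with all libraries. Dcpp2 and Klk1b26, genes of the salivary gland, rest on WT library 1: Dcpp2 stood at 521 there and at 0 in the other 3 libraries, and the Klk1b26 mean in WT was 194 ± 275 (SD, n = 2) against 0 in the cKO.

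With these 3, 384 genes were listed at 0 h, 297 as higher and 87 as lower in the cKO. Those that did not pass the adjusted threshold include the proliferation marker Mki67 at 662 ± 229 in cKO and 257 ± 52.6 in WT (SD, n = 2), the interferon-stimulated Rsad2 at 189.6 ± 68.1 and 90.1 ± 28.3, and the complement gene C1qc, a macrophage marker, at 499 ± 178 and 910.4 ± 361. By list, 3 genes of G2/M and mitosis, 3 interferon-stimulated genes and 2 memory-like genes were listed as higher, and monocyte and macrophage markers split into 2 higher and 3 lower, none called. Eif5b and the erythroid gene Alas2 (higher) and Tnf (lower), the only listed members of the translation factor, erythroid and cytokine lists, were not called either. Some higher listings rest on cKO library 2. Eif5b stood at 2045 and 5096 in cKO libraries 1 and 2, against 2054 and 1965 in WT. Alas2 was higher in both, at 193 and 254 against 104 and 71.0. Over all listed genes, cKO library 2 held 674416 reads and the other libraries between 423873 and 441827. DESeq2 on the recovered reads called 3 genes with all libraries, and 79, 2, 1 and 7 without cKO library 1, cKO library 2, WT library 1 and WT library 2.

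The comparison at 3 h asks how the knockout altered early activation. Interferon-stimulated genes were higher in cKO cells: 19 of 27 were listed, all 19 as higher. Over all genes 12 of them were called, and 18 when adjusted over the list alone. Gbp2, a GTPase of antimicrobial defence, rose to 7011 ± 804 in the cKO from 869 ± 327 in WT (SD, n = 2), and Zbp1, a nucleic acid sensor, to 1437 ± 32.3 from 345 ± 99.0 (SD, n = 2). Gbp4 and the signalling factor Stat2 rose as well, with means 3.68 and 2.62 times those of WT. Compared with the direction of the other listed genes, the list differed by Fisher's exact test (adjusted p = 8.9e-05).

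Genes of helper and effector T cells were also higher at 3 h: 12 of 25 were listed, all 12 as higher, 8 of them called and 10 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.00348). The protease gene Gzma rose to 535 ± 66.7 from 192 ± 26.5 (SD, n = 2). The regulatory T cell factor Foxp3 rose to 508 ± 23.0 from 213 ± 12.1, and the interleukin-12 receptor gene Il12rb2 to 595 ± 134 from 176 ± 95.5. Among cytokines, 12 of 22 were listed and 8 called, 9 when adjusted over the list alone. Ifng rose to 443 ± 197 from 53.3 ± 17.6 (SD, n = 2), Il17a to 480.4 ± 242 from 61.1 ± 20.2 and Ccl5 to 1027 ± 100.3 from 414 ± 44.8, with Il21, Il13 and Il5 also higher. Lta fell to 925 ± 143 from 2007 ± 312 (SD, n = 2), and Tnf was the other cytokine gene called lower. The direction of the cytokine list did not pass Fisher's exact test (adjusted p = 0.106).

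Of the memory-like genes, 7 of 20 were listed, all as higher, and 3 called (adjusted p = 0.071 by Fisher's exact test). The called genes were Ly6c1, the NKG2D receptor gene Klrk1 and the interleukin-2 receptor gene Il2rb, with means 6.18, 3.04 and 1.51 times those of WT. The activation receptors Ctla4, Tnfrsf9 and Tnfrsf4 were the 3 called among 6 listed early activation genes, with Ctla4 at 1177 ± 323 against 390.1 ± 84.2 (SD, n = 2). Slc3a2, a subunit of amino acid transporters, rose to 16623 ± 817 from 8601 ± 679 (SD, n = 2) and was the 1 gene called of 4 listed in its list. Of 4 listed p53 and apoptosis genes, Pmaip1 rose and Bbc3 fell, to 469 ± 81.9 from 829 ± 18.8 (SD, n = 2). Myc was listed at 3 h only, at 21244 ± 2349 in cKO and 16761 ± 2387 in WT (SD, n = 2). In the authors' deposited table the log2 fold change of Myc was 0.34 (adjusted p = 0.714).

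No gene was called at 3 h in the lists of ribosome biogenesis (6 listed, all higher, such as Bop1), aminoacyl-tRNA synthetases (3 listed, all higher, such as Wars), MYC partners and targets (3 listed, all higher), other tRNA modification enzymes (3 listed), glycolysis (2 listed, Hk1 and Pfkp), G1/S (2 listed, Orc1 and Ccnd3), the integrated stress response (2 listed), naive T cells (2 listed, Satb1 and Il7r) or monocytes (1 listed, Cst3). Markers of CD8, NK and gamma-delta T cells had 4 listed, all higher. Ccl5 was called, and Ncr1, Klrb1c and Tcrg-C1 were not. Ncr1 stood at 56.7 ± 23.6 in cKO and 13.2 ± 1.81 in WT (SD, n = 2).

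In all, 253 genes were called at 3 h, 176 higher and 77 lower in the cKO, among 1091 listed, 570 as higher and 521 as lower. By limma, adjusted over the listed genes alone, 414 were called, 206 higher and 208 lower. By edgeR on the recovered reads 0 were called, against 1091 at an unadjusted p under 0.05 by the authors' test. Trmt61a stood at 117 ± 26.3 in cKO and 1140.4 ± 10.3 in WT (SD, n = 2). The extremes were genes of other organs. Of 27 listed pancreatic acinar genes, all higher in the cKO, 23 were called. Their summed values were 1694 and 11271 in cKO libraries 1 and 2 and 89.0 and 192 in the WT libraries. The 8 highest by the naming rule, Amy2a1, Try4, Pnlip, Cpb1, Pnliprp1, Ctrb1, Cela2a and Try5, all encode pancreatic enzymes or relatives. Of 17 listed submandibular gland genes, all lower in the cKO, 9 were called, with sums of 11222 and 939.97 in WT libraries 1 and 2 and 35.2 and 41.0 in the cKO. Besides Trmt61a, the lowest called genes were Klk1b26, Klk1b16, Klk1b9, Crisp3, Klk1b11, Klk1b4 and Klk1b5. Of 30 listed immunoglobulin genes, 29 were lower in the cKO and none was called, although all 30 had an unadjusted p under 0.05. Their sums were 356 and 403 in the cKO libraries, 662 in WT library 1 and 3517 in WT library 2, which carries most of the difference. With the genes of both organs and immunoglobulins left out, 221 genes stayed called.

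The interferon-stimulated genes summed to 27554 and 26305 in the cKO libraries and to 8814 and 5709 in the WT libraries at 3 h. DESeq2 on the recovered reads called 137 genes at 3 h with all libraries, and 41, 70, 80 and 81 without cKO library 1, cKO library 2, WT library 1 and WT library 2. In the same order it called 7, then 3, 3, 5 and 3 interferon-stimulated genes, and 4, then 0, 2, 3 and 2 helper and effector genes. For cytokines these counts were 5, then 0, 4, 3 and 2, for memory-like genes 1, then 0, 1, 1 and 1, and for early activation genes 1, then 0, 1, 1 and 0. Of the CD8, NK and gamma-delta markers it called 1, then 0 in each fit without a library, of the p53 and apoptosis genes 0 in every fit, and of the amino acid genes 1 in every fit.

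**Figure D2:**
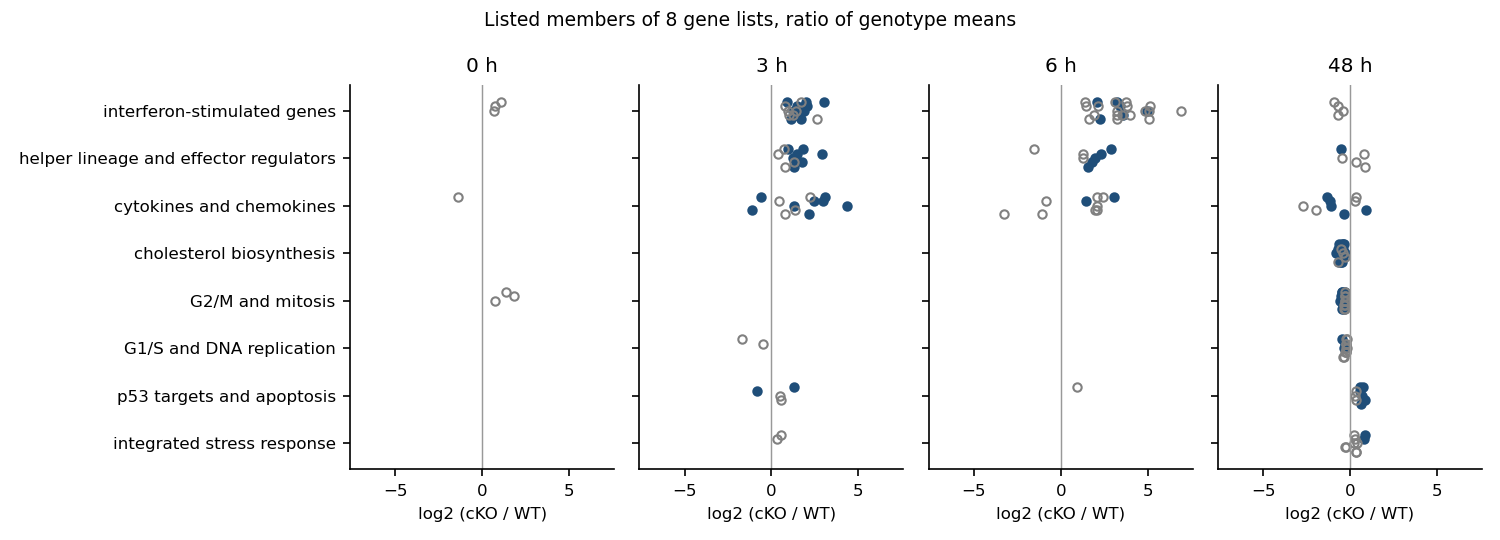
log2 ratio of the cKO mean to the WT mean (horizontal axis) of the listed members of 8 gene lists at 0, 3, 6 and 48 h, 1 point per gene; filled points are genes with the authors' adjusted p under 0.05 and open points are not. The 19 interferon-stimulated genes of 3 h and the 24 of 6 h lie to the right of 0, and the 20 cholesterol biosynthesis genes of 48 h to its left.

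The comparison at 6 h, the time of the m1A measurement, asks which genes differed as the cells grew. Of 27 interferon-stimulated genes, 24 were listed, all as higher in the cKO, 6 of them called and 24 when adjusted over the list alone (Fisher's exact test, adjusted p = 7.7e-07). Zbp1 rose to 2409 ± 1696 from 256 ± 131 (SD, n = 2), the RNA sensor gene Dhx58 to 455 ± 494 from 42.8 ± 6.66. Oas1a rose to 247 ± 286 from 20.9 ± 9.44 (SD, n = 2) and Ifi44 to 139.7 ± 187 from 4.54 ± 0.311, so that the spread in the cKO was as wide as the mean in the last 3. The list summed to 41691 in cKO library 1 and 8457 in cKO library 2, against 4840.1 and 2785 in the WT libraries. DESeq2 on the recovered reads called 8 of its genes, and 0, 17, 7 and 4 without cKO library 1, cKO library 2, WT library 1 and WT library 2.

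Of the helper and effector genes, 8 were listed, 7 as higher, and 5 called, all higher (Fisher's exact test, adjusted p = 0.0949). Tbx21, the type 1 helper cell regulator, rose to 1177 ± 254 from 159 ± 62.6 (SD, n = 2), Gzma to 369 ± 81.5 from 75.4 ± 5.70, and Il12rb2 and Tigit rose as well. Adjusted over the list alone, 7 passed. Of these genes DESeq2 on the recovered reads called only 1, and 0, 0, 1 and 0 without cKO library 1, cKO library 2, WT library 1 and WT library 2. Of 11 listed cytokine genes, 8 were higher, and 7 without cKO library 2, since Il5 stood at 19.2 ± 27.1 against 0 (SD, n = 2). Ifng and Ccl5 were called, at 469 ± 298 against 56.0 ± 53.6 and 418 ± 54.7 against 150.1 ± 8.74 (SD, n = 2), and Ccl5 was also the only listed CD8 and NK cell marker. DESeq2 called no cytokine gene with all libraries and 1 without WT library 1, and in each other fit none. Ly6c1 was the memory-like gene called of 3 listed, while DESeq2 called 0, then 0, 0, 1 and 0 of these. The highest called genes included Ptgs2, which encodes cyclooxygenase-2, at 364 ± 271 against 37.2 ± 20.6, together with Serpina3f, Sdc3 and Jaml.

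Among genes lower at 6 h, the mitochondrial ribosomal RNA mt-Rnr1 fell to 6366 ± 2081 from 20654 ± 846 (SD, n = 2), the growth factor gene Pdgfb to 313 ± 53.6 from 1011 ± 255, and Sumo2, Aldh7a1 and Fer1l5 fell as well. Immunoglobulin genes had 20 listed and 2 called, Igkc at 1021 ± 207 against 2962 ± 392.4 (SD, n = 2) and Ighg3 at 50.9 and 72.8 in the cKO libraries, 132 in WT library 1 and 647 in WT library 2. The immunoglobulin sums were 1145 and 1569 in the cKO, 3320.3 in WT library 1 and 5514 in WT library 2. Of the B cell markers, 3 were listed, Igkc and Blnk as lower and H2-Eb1 as higher, and DESeq2 called none of them in any fit. Nothing was called among listed genes of early activation (3 listed, with Il2ra at 16007 ± 1513 in cKO and 27859 ± 12571 in WT), naive T cells (2), MYC partners (Mycn), glycolysis (Gapdh), amino acid transport (Slc3a2), histones (Hist1h1d), p53 targets (Pmaip1), heat shock (Hspa1a) or platelets (Ppbp).

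In all, 83 genes were called at 6 h, 59 higher and 24 lower in the cKO, among 740 listed, 359 as higher and 381 as lower. By limma and by edgeR on the recovered reads 0 were called, so that no list had a call with edgeR, although all 740 had an unadjusted p under 0.05 by the authors' test. Trmt61a stood at 157 ± 33.0 in cKO and 1483 ± 825 in WT (SD, n = 2). Pancreatic acinar genes had 21 listed, all higher in the cKO and 5 called, with sums of 249 and 2336 in cKO libraries 1 and 2 against 24.97 and 80.3 in WT. Submandibular gland genes had 16 listed, all lower and 3 called, with sums of 2789.9 and 230.5 in WT libraries 1 and 2 against 27.8 and 36.4 in the cKO. With these and the immunoglobulin genes left out, 73 genes stayed called. Of the authors' 83 calls, only 10 were also called by DESeq2 on the recovered reads with all libraries. DESeq2 on the recovered reads called 29 genes, and 7, 41, 17 and 11 without cKO library 1, cKO library 2, WT library 1 and WT library 2.

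**Figure D3:**
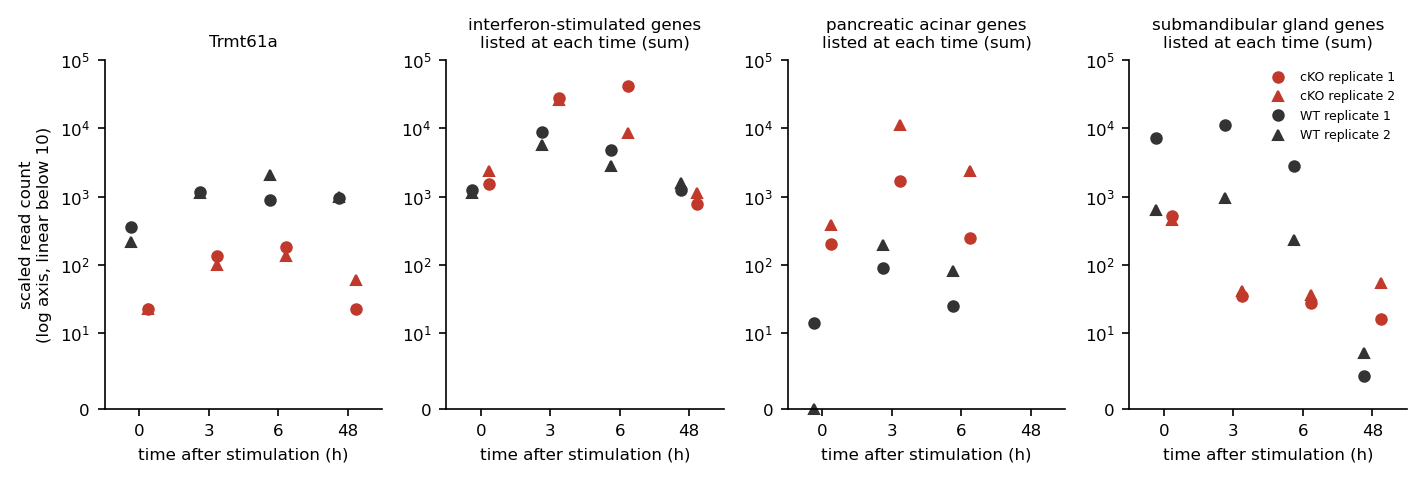
Scaled read count per RNA-seq library (vertical axis, logarithmic, linear below 10) by time, for Trmt61a and for the sums of the interferon-stimulated, pancreatic acinar and submandibular gland genes listed at each time; the genes summed differ between times, red is cKO, dark is WT, circles are replicate 1 and triangles replicate 2. At 6 h the interferon-stimulated sum is 41691 in cKO replicate 1 and 8457 in cKO replicate 2.

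The comparison at 48 h asks how the knockout altered cells in the phase of division. Cholesterol biosynthesis genes were lower in cKO cells: 20 of 21 were listed, all as lower, 16 of them called and 20 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.00146). Hmgcs1 fell to 3102 ± 431 from 4890.1 ± 47.7 (SD, n = 2), Lss to 1739.5 ± 245 from 2792 ± 186 and Mvd to 965 ± 209 from 1691 ± 54.8. Cell cycle genes were lower too: 20 of 30 genes of G2/M and mitosis were listed, all as lower, 11 called and 19 when adjusted over the list alone (adjusted p = 0.00146 by Fisher's exact test). Birc5, which encodes survivin, fell to 1736 ± 100.3 from 2388 ± 0.0555 (SD, n = 2), the mitotic kinase gene Plk1 to 1483 ± 137 from 2108 ± 194, and the cyclin genes Ccnb2 and Ccnb1 to 0.672 and 0.754 times WT.

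Of 32 genes of G1/S and DNA replication, 14 were listed, all as lower, 3 called and 12 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0184): Tk1, Mcm7 and Ccna2, at 0.718, 0.805 and 0.795 times WT. Targets of p53 and apoptosis genes were higher, with 9 of 22 listed, all as higher, 6 called and 9 when adjusted over the list alone (adjusted p = 0.00146 by Fisher's exact test). The cell cycle inhibitor gene Cdkn1a rose to 5291 ± 1060.5 from 3130.3 ± 132 (SD, n = 2), Trp53inp1 to 2862 ± 543 from 1906 ± 311, Bbc3 to 984 ± 205 from 614 ± 38.1 and Pmaip1 to 337 ± 11.7 from 184 ± 32.7. In the integrated stress response list, 10 of 20 were listed, 8 as higher and 2 as lower (Fisher's exact test, adjusted p = 0.0319). Ddit3, which encodes CHOP, was called at 1069 ± 75.2 against 595 ± 22.6 (SD, n = 2) and Atf5 at 1336 ± 88.4 against 776 ± 119. Adjusted over the list alone, 8 passed.

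The type 2 helper cytokines Il4 and Il13 and the growth factor gene Il3 fell, Il4 to 265 ± 113 from 579 ± 3.75 (SD, n = 2) and Il3 to 250.0 ± 67.5 from 638 ± 116. Tnfsf8 rose to 8049 ± 1289 from 4249 ± 746 (SD, n = 2). Of 9 listed cytokine genes 5 were called, Lta being the other lower one. Heat shock and unfolded protein response genes had 9 listed, all as lower, and 5 called, with Hspa8 at 51974 ± 338 against 65076 ± 1611 (SD, n = 2), Calr, Sdf2l1, Manf and Hsp90b1. Glycolysis genes had 8 listed, all as lower, with Gapdh, Pgam1 and Tpi1 called. Gapdh stood at 1062 ± 10.3 against 4755 ± 373 (SD, n = 2); its reads were not separated here from those of its processed copies. Oxidative phosphorylation had 9 listed, all as lower, with Cox4i1 and Cox5a called. For each of these 3 lists Fisher's exact test of direction gave an adjusted p of 0.0949. Every listed member was already lower, so no more extreme split towards lower was possible. The listed share, a different question chosen after seeing the data, passed Fisher's exact test for each. Its adjusted p was 7.0e-04 for heat shock, 0.00245 for glycolysis and 0.00308 for oxidative phosphorylation.

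The direction of the other lists at 48 h, where tested, did not pass Fisher's exact test. Early activation genes had 5 listed and 4 called, Egr1 and Egr2 as higher and Icos and Jund as lower. Translation factors had 7 listed, with Eif5a called lower and Eif3c higher. Single genes were called for amino acid metabolism (Psph, lower), naive T cells (Klf6, higher), memory-like genes (Ahnak, higher) and helper and effector genes (Eomes, lower). None was called among MYC partners and targets (4 listed, all lower, with Ldha at 38529 ± 1729 against 43575 ± 442), interferon-stimulated genes (4 listed, all lower, with Isg15 at 75.4 ± 29.5 against 145 ± 12.8), ribosome biogenesis (3), histones (3), aminoacyl-tRNA synthetases (Eprs), other tRNA modification enzymes (Qtrt2) or gamma-delta T cell markers (Tcrg-C2). The 3 histone genes and Tcrg-C2 were set aside from the authors' adjustment, so they could not have been called.

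In all, 236 genes were called at 48 h, 83 higher and 153 lower in the cKO, among 1195 listed. By limma 1091 were called, adjusted over the listed genes alone, which had all been selected at an unadjusted p under 0.05. By edgeR on the recovered reads, adjusted over 9940 genes, 7 were called. Of the 236, 26 had an absolute log2 fold change of at least 1. Trmt61a stood at 41.7 ± 26.7 in cKO and 969 ± 20.3 in WT (SD, n = 2). The highest called genes were Rpl30-ps10, Trim66, Slc4a11, Lrrk2, Anxa3, Eng, Rgs2 and Eps8l1, with Rgs2 at 539 ± 19.2 against 248 ± 9.09 (SD, n = 2). The lowest, besides those above, were Ckb, Epas1 and Efna5. No pancreatic gene and 1 submandibular gland gene, Bpifa2, were listed at this time, and all 236 calls lie outside the genes of other organs and the immunoglobulins.

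DESeq2 on the recovered reads called 206 genes at 48 h, and 51, 205, 13 and 21 without cKO library 1, cKO library 2, WT library 1 and WT library 2. In the same order it called 13, then 6, 15, 1 and 2 cholesterol genes, 11, then 0, 8, 0 and 0 genes of G2/M, 3, then 1, 3, 0 and 0 of G1/S, and 4, then 1, 6, 1 and 2 of the p53 list. The counts were 5, then 1, 3, 0 and 0 for heat shock and unfolded protein response, 2, then 2, 3, 1 and 0 for the integrated stress response, 2, then 0, 1, 0 and 0 for oxidative phosphorylation, and 3, then 2, 7, 1 and 1 for glycolysis. For cytokines they were 5, then 1, 3, 1 and 2, for early activation 5, then 1, 3, 0 and 0, and for translation factors 2, then 0, 3, 0 and 0. Memory-like genes had 3, then 1, 3, 0 and 1, helper and effector genes 2, then 0, 1, 0 and 0, naive T cell genes 1, then 1, 1, 0 and 0, and amino acid genes 1, then 0, 1, 0 and 0.

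Directions were compared between the times. Of 345 genes listed at both 3 and 6 h, 344 had the same direction (exact binomial test, two-sided, p = 9.7e-102), 198 higher and 146 lower in the cKO. Sumo2 was the exception. Of the genes called at both times, all 48 had the same direction, among them Zbp1, Tbx21, Gzma and Ifng. Between 3 and 48 h, 123 genes were listed at both, 75 in the same and 48 in the opposite direction (exact binomial test, p = 0.0187), and 39 of the 48 were higher at 3 h and lower at 48 h. Among the 13 genes called at both of these times no excess was left, with 7 in the same and 6 in the opposite direction (p = 1 by exact binomial test). Between 6 and 48 h, 25 of 61 shared genes had the same direction, which did not differ from chance (Fisher's exact test, p = 0.161). Genes listed at 0 h shared direction with 3 h in 37 of 46 (p = 4.1e-05, exact binomial test), with 6 h in 19 of 30 and with 48 h in 25 of 46. Genes are not independent replicates, and the genes of other organs are part of these counts. Submandibular gland sums were higher in WT library 1 than in WT library 2 at 0 h (7076 and 638), 3 h and 6 h, and libraries of the same number could share a source, in which case the times are not independent and the p-values are too small. The named genes listed at 3 or more times were Klk1b26, Klk1b5, Klk1b27, Crisp3, Prol1, Reg2, Gm4779 and Gm33707. The last, a predicted gene on chromosome 3, stood at 195 ± 68.7 in cKO and 1.46 ± 0.663 in WT at 3 h and at 170.5 ± 10.1 and 0 at 48 h (SD, n = 2).

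The tRNA-seq comparison follows the tRNA pool of WT cells from rest into activation. tRNA made up 66.7% ± 0.0469 (SD, n = 2) of library reads at 0 h, 85.1% ± 2.93 at 6 h, 90.5% ± 1.42 at 18 h and 88.7% ± 2.19 at 48 h. Ribosomal RNA took 21.3% ± 0.513 at 0 h and 7.68% ± 1.80 at 48 h, and U RNA (small nuclear RNA) 11.8% ± 0.574 and 3.27% ± 0.357 (SD, n = 2). Each of these changes against 0 h exceeded the spread between duplicates, with an exact permutation p of 0.333 (two-sided), the smallest that 2 against 2 libraries allow. Scaled to library totals, 42 of 49 isoacceptors rose and none fell by 6 h by edgeR, with 42 at an unadjusted p under 0.05. In the same way 42 rose and 1 fell by 18 h, and 39 rose and 1 fell by 48 h. The median log2 change was 0.38, 0.45 and 0.41 at these times. On the tRNA scale, where these shifts are removed, 3 rose and 5 fell by 6 h, 10 rose and 6 fell by 18 h, and 11 rose and 7 fell by 48 h.

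Glutamine tRNA Gln-TTG rose from 8573 ± 502 RPM at 0 h to 13570 ± 122 at 6 h, 17704 ± 1187 at 18 h and 15114 ± 576 at 48 h (SD, n = 2), and by 0.29, 0.62 and 0.41 log2 units on the tRNA scale (edgeR adjusted p = 0.0414, 5.4e-04 and 0.00402). At 6 h the next were Leu-CAA, Thr-TGT, Ser-TGA and Leu-TAA, with log2 changes from 0.59 to 0.54, of which Leu-CAA and Ser-TGA also rose on the tRNA scale. At 18 h they were Gln-CTG (0.83), Tyr-GTA (0.76), Gly-TCC (0.73) and Thr-TGT (0.73), of which Tyr-GTA did not pass on the tRNA scale (edgeR adjusted p = 0.0541). At 48 h Ser-CGA (0.88) stood above Gln-TTG (0.82), followed by Gln-CTG (0.75), Ser-GCT (0.72) and Leu-CAA (0.71), all of which rose on both scales.

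Selenocysteine tRNA SeC-TCA, which serves the synthesis of selenoproteins, fell from 3944 ± 454 RPM at 0 h to 1504 ± 183 at 18 h and 1711 ± 41.5 at 48 h (SD, n = 2), by log2 changes of -1.39 and -1.21 (edgeR adjusted p = 5.6e-13 and 3.4e-11), and it fell on the tRNA scale at all 3 times. Its share of tRNA reads was 0.592% ± 0.0686 at 0 h and 0.193% ± 0.00948 at 48 h (SD, n = 2). Initiator methionine tRNA depended on the scale: its log2 change was 0.28, 0.18 and -0.07 at 6, 18 and 48 h with library totals (edgeR adjusted p = 0.00546, 0.0638 and 0.492) and -0.10, -0.25 and -0.47 on the tRNA scale (edgeR adjusted p = 0.559, 0.0450 and 0.00291). Its share of tRNA reads was 3.54% ± 0.458 at 0 h and 2.54% ± 0.0625 at 48 h (SD, n = 2). Arg-TCT, with log2 changes of 0.13, 0.01 and -0.06 by library totals that did not pass, fell by 0.25, 0.42 and 0.46 on the tRNA scale at 6, 18 and 48 h. Without 0 h replicate 1 or 6 h replicate 1 the rise of iMet-CAT by 6 h no longer passed, at 0.15 and 0.23 (edgeR adjusted p = 0.160 and 0.0561). On the tRNA scale Trp-CCA, Asp-GTC and Arg-ACG also fell by 6 h, Glu-TTC and Thr-CGT by 18 h, and Glu-TTC and Trp-CCA by 48 h, although by library totals Arg-ACG rose at 6 h and Glu-TTC at 18 h.

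Shares by the first anticodon base moved little. Anticodons with T there made up 20.4% ± 0.699 of tRNA reads at 0 h, 22.1% ± 0.163 at 18 h and 19.9% ± 0.167 at 48 h (SD, n = 2), and those with A, read as inosine, 14.7% ± 0.439 at 0 h and 15.9% ± 0.169 at 48 h. Those with C stood at 31.7% ± 1.47 and 31.2% ± 0.393 at 0 and 48 h, and those with G at 29.1% ± 0.0535 and 30.2% ± 0.801. No exact permutation test of these shares could go below 0.333. Among 168 tRNA genes tested singly, where reads of near-identical copies may be exchanged, 96 rose and none fell by 6 h (edgeR; 103 at an unadjusted p under 0.05), 120 rose and 2 fell by 18 h, and 118 rose and 5 fell by 48 h. On the tRNA scale 16 of these genes rose and 5 fell by 6 h, 48 rose and 27 fell by 18 h, and 57 rose and 38 fell by 48 h. By library totals fewer isoacceptors changed between later times than against 0 h. On the tRNA scale 8, 16 and 18 changed against 0 h at 6, 18 and 48 h. From 6 to 18 h 6 changed on that scale, fewer than each of these. From 18 to 48 h 12 changed on it, more than the 8 but fewer than the others. By library totals 12 rose and 1 fell from 6 to 18 h (4 and 2 on the tRNA scale), 13 in all. From 18 to 48 h, 5 rose and 8 fell (7 and 5 on the tRNA scale), with 13 in all and 5 without 48 h replicate 2. Of the tRNA genes, 66 rose and 3 fell from 6 to 18 h (42 and 29 on the tRNA scale), with 69 in all and 40 without 6 h replicate 2. From 18 to 48 h, 25 rose and 15 fell (30 and 14 on the tRNA scale), these 40 becoming 7 without 48 h replicate 1, 1 without 48 h replicate 2 and 26 without either 6 h replicate.

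**Figure D4:**
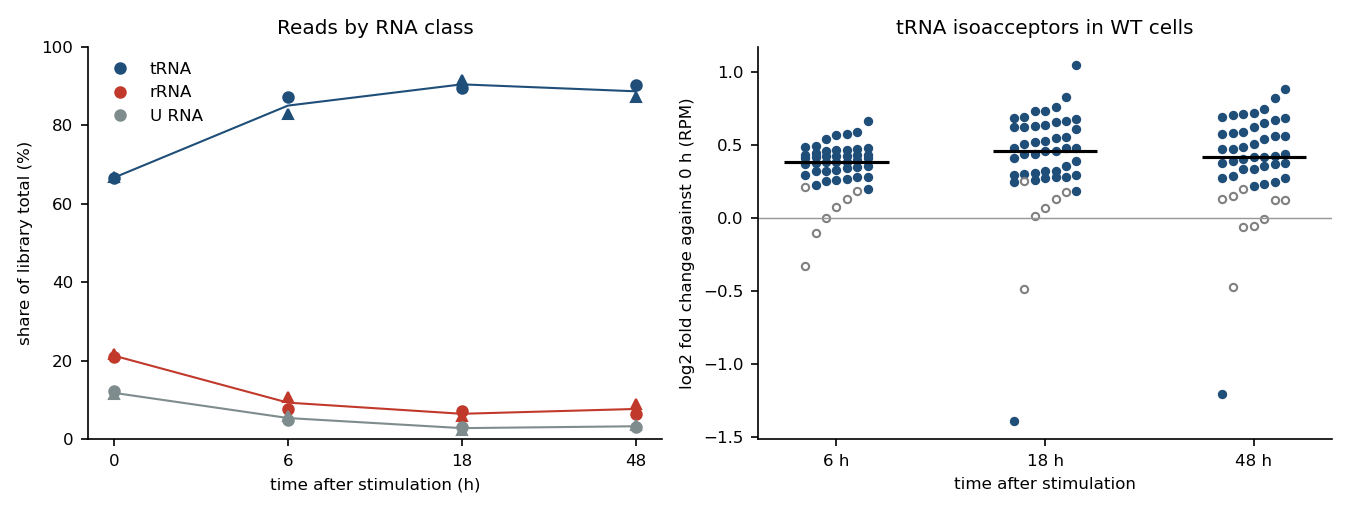
Left, share of each tRNA-seq library's reads in percent taken by tRNA, rRNA and U RNA by time, circles for replicate 1, triangles for replicate 2 and lines through the means; right, log2 change of 49 isoacceptors against 0 h by library totals, filled where edgeR's adjusted p is under 0.05, with a bar at the median. The tRNA share goes from 66.7% to 88.7%, and the medians are 0.38, 0.45 and 0.41; on the tRNA scale 3, 10 and 11 isoacceptors rose at the 3 times and 5, 6 and 7 fell.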

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

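The tests of explanations in this part were chosen after the results they concern had been seen.

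The expression of 6 genes was called with opposite directions at 3 and 48 h, every cKO library lying on 1 side of both WT libraries at one time and on the other side later; whether the effects differ was not tested. On the recovered reads DESeq2 called only 2 of the 6 at both times, Elovl6 and Ifi47, and not Bbc3, Il13, Eomes or Ulbp1 at 3 h. Bbc3, which encodes the apoptosis inducer PUMA, had a log2 ratio of cKO to WT of -0.82 at 3 h and 0.68 at 48 h. The cytokine gene Il13 stood at 2.46 at 3 h and -1.09 at 48 h. The transcription factor gene Eomes stood at 1.31 and -0.51 at these times. Elovl6, a fatty acid elongase gene, stood at 1.65 and -0.59. Ifi47, an interferon-inducible GTPase gene, stood at 1.54 at 3 h, 2.07 at 6 h and -0.37 at 48 h. Ulbp1, an NKG2D ligand gene, stood at -1.13 at 3 h and 0.56 at 48 h.

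Transcripts of other organs divided the genotypes at 3 h: 27 pancreatic acinar genes were listed as higher in the cKO and 17 submandibular gland genes as lower. A change of these genes alike in both libraries of a genotype is argued against, since these differed by a median log2 ratio of at least 2.64. That spread cannot exclude a change in the T cells that differs between libraries. The interferon-stimulated genes of 6 h differed as widely between cKO libraries, by a median of 2.97. Pancreas and gland RNA carried in unequal amounts may account for the pattern. Both cKO libraries held the pancreatic genes, with sums of 1694 and 11271 against 89.0 and 192 in WT. The ratio of cKO library 2 to cKO library 1 had an SD of only 0.65 over the 27 pancreatic genes around its median of 2.64, close to 1 common factor. The most abundant, Ctrb1, stood at 253 and 1773 in the cKO libraries and at 2.90 and 2.99 in the WT libraries; of the listed genes, 2 pancreatic and 1 gland gene reached 10 in the other genotype, and none is in another list. Isolation of naive CD4 cells would remove such cells, and whether it removes their free RNA was not tested.

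Interferon-stimulated genes were higher in the cKO at 3 h (19 listed) and 6 h (24 listed). Pancreatic RNA or cells as their source is argued against, since at 3 h the median log2 ratio of cKO library 2 to library 1 was -0.34 for these genes (SD 0.66) and 2.64 for the pancreatic genes. A response in cKO library 1 may account for much of the excess at 6 h, where the median log2 ratio of library 1 to library 2 was 2.97 (SD 1.22), with summed values of 41691 and 8457 against 4840.1 and 2785 in the WT libraries. Antigen-experienced cells among the naive cKO cells cannot be told apart from a response after stimulation. Of 45 memory-like and effector genes, 2 were listed as higher at 0 h, Il2rb and Ahnak. The rest have no value in that table. Ahnak rested on cKO library 2, at 1844 and 3689 in cKO libraries 1 and 2 against 1729 and 1774 in WT. A stronger interferon-type response of cKO cells is 1 biological explanation, and it stays open and untested. A difference in cell composition was not tested either. At 3 h all 4 listed markers of CD8, NK and gamma-delta T cells were higher in the cKO, with 1 called. The direction of that list did not pass Fisher's exact test (adjusted p = 0.265).

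Nearly all tRNAs gained reads relative to the library total after activation. Whether fewer rRNA and U RNA reads per library caused it cannot be told apart from a gain of tRNA: the log2 change of the tRNA share at 48 h, 0.41, and the median isoacceptor change of 0.41 come from the same library totals and would match in either case. A different size selection or RNA quality of the 0 h libraries cannot be told apart from activation, because each time has its own libraries: the log2 changes of the rRNA and U RNA shares differed by 0.38, and a gain of tRNA in the cells would lower both as well. A gain of cellular tRNA relative to rRNA and U RNA after activation is the biological explanation, and it was not tested.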

How the results depend on the processing

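DESeq2 and edgeR on recovered reads, the gene sets left out, the listed-share test, the shared calls at an adjusted p under 0.05 and, for tRNA, TMM, DESeq2 and the crossed block were chosen after seeing the data. The fits without 1 library assume that the lone sample left varies like the other groups, and the causes of the changes below were not tested.

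RNA-seq calls, 3, 253, 83 and 236 at 0, 3, 6 and 48 h, became 1, 161, 47 and 135 at an adjusted p under 0.01. Under limma, adjusted over the listed genes alone, they were 4, 414, 0 and 1091 at the 4 times. The 0 at 6 h stands against 83 by the authors' test and 740 at an unadjusted p under 0.05. With edgeR on recovered reads the calls were 6, 0, 0 and 7, so that at 3 h Trmt61a was not called either. In simulated data with the spread of 3 h, edgeR recovered 0% of 1.5-fold, 10.8% of 2-fold and 50.9% of 4-fold changes. Most simulated genes were unchanged, while the real fit held only selected genes, so the simulation cannot say why edgeR gave 0 calls. With DESeq2 they were 137 at 3 h and 29 at 6 h, of which 123 and 10 were shared with the authors. With DESeq2 and a replicate block they were 1, 92, 32 and 91 at the 4 times. Limma with the block gave 3, 325 (144 higher, 181 lower), 106 and 1137. Thus 0 limma calls at 6 h became 106, of which 46 were shared with the authors. Leaving out the genes of other organs and immunoglobulins gave 1 at 0 h, and an absolute log2 fold change of at least 1 gave 26 at 48 h. Without 1 library each, DESeq2 called 1 to 79 genes at 0 h, 41 to 81 at 3 h, 7 to 41 at 6 h and 13 to 205 at 48 h. The log2 change of Klk1b5 at 0 h ran from -5.46 without WT replicate 2 to 2.65 without WT replicate 1, and that of Hspa1a at 6 h from -2.46 without WT replicate 1 to 0.34 without WT replicate 2. Of 40 tests of list direction 8 passed. The listed share, a different question, passed in 19 of 104 tests. The direction passed in 7 at a mean value of at least 100, and 7 at an absolute log2 fold change of at least 1, of which only 3 were among the 8. The 344 genes sharing direction at 3 and 6 h became 29 at an adjusted p under 0.01 in both tables and 48 under 0.05, as fewer genes were counted.

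For tRNA isoacceptors, 42, 43 and 40 calls against 0 h at 6, 18 and 48 h became 4 (2 higher, 2 lower), 16 (3 and 13) and 17 (10 and 7) with median-centred values, 8, 16 and 18 with TMM, and 8, 9 and 16 with DESeq2 size factors, settings that remove the common shift by construction. The 13 calls from 6 to 18 h (12 higher, 1 lower) became 6 with TMM (4 and 2), 7 with DESeq2 size factors (4 and 3), 14 median-centred (1 and 13) and 3 to 17 without 1 library; those from 18 to 48 h became 5 to 13. A replicate block gave 42, 45 and 40 calls against 0 h, 14 from 6 to 18 h (15 with the 6 h replicates exchanged) and 13 from 18 to 48 h. For tRNA genes, 96 at 6 h, all higher, became 61 median-centred (12 higher, 49 lower), 21 with TMM (16 and 5) and 18 with DESeq2 size factors (15 and 3); 122 at 18 h became 75 and 78 with the last 2. Median-centred values gave 140 and 146 at 18 and 48 h, of which 110 and 115 fell. For tRNA genes this setting overshot the common shift. Its median log2 change was -0.26, -0.61 and -0.75 at 6, 18 and 48 h, against 0.36, 0.55 and 0.62 by library totals. It was also -0.32 from 6 to 18 h and -0.14 from 18 to 48 h. Among isoacceptors it was -0.12 from 6 to 18 h. The excess of falls with median-centred values therefore follows from the setting and shows no reversal. From 6 to 18 h, 69 (66 higher, 3 lower) became 113 median-centred (31 and 82), 71 with TMM (42 and 29), 72 with DESeq2 size factors (39 and 33) and 40 to 82 without 1 library. From 18 to 48 h, 40 (25 and 15) became 57 median-centred (11 and 46) and 1 to 57 without 1 library. Initiator methionine iMet-CAT turned to -0.0558, -0.10 and -0.10 at 6 h and to -0.34, -0.25 and -0.27 at 18 h with median-centred values, TMM and DESeq2 size factors, and ran at 48 h from -0.19 without 0 h replicate 1 to 0.0738 without 0 h replicate 2. The other tRNA settings kept the counts within 1.5 times. The m1A change was -54.9 points among tRNAs above the WT median and -1.45 as a log2 ratio.

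No paired analysis of m1A and no left-out replicate was possible because the table gives 1 value per genotype. Averaging m1A per anticodon and leaving out mitochondrial tRNAs were not run, since the values are already per anticodon and no mitochondrial tRNA is present; DESeq2 size factors and an unfiltered test were not run on RNA-seq, since its tables hold selected genes.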

Other observations

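The genes in this part were chosen after their values were seen, as was the test of tRNA gene copies; the tests of m1A loss against tRNA change were set beforehand.

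Some genes of antigen processing were called higher in cKO cells at 3 or 6 h, with no list of such genes fixed or tested. Tapbp, which encodes tapasin, stood at 3475 ± 76.0 in cKO and 2241 ± 164 in WT at 3 h (SD, n = 2) and at 4922 ± 1650.2 and 1545 ± 242 at 6 h, called both times. Psme2, a proteasome activator gene, was called at 3 h but not at 6 h, standing at 3 h at 2720.4 ± 164 and 1728 ± 103 (SD, n = 2). The immunoproteasome genes Psmb8 and Psmb10 were called at 6 h but not at 3 h, Psmb8 at 1884 ± 459 and 544 ± 198 (SD, n = 2) and Psmb10 at 991 ± 334 and 269.8 ± 20.04. At 48 h all 4 were listed as lower in the cKO and none was called. The large mitochondrial ribosomal RNA mt-Rnr2 stood at 11303 ± 3287 in cKO and 33605 ± 3814 in WT at 6 h (SD, n = 2), called like mt-Rnr1.

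A pair of predicted genes on chromosome 3 was close to 0 in WT and present in cKO cells at 3, 6 and 48 h. Gm33707 (60769887 to 60770455) stood at 137 ± 62.8 in cKO and 0 in WT at 6 h (SD, n = 2), and Gm38326 (60788361 to 60794730) at 10.2 ± 1.88 and 0. Mbnl1, a splicing regulator gene at 60472830 to 60629750, was listed as higher at 0, 3 and 48 h and called at 48 h, at 12349 ± 502 in cKO and 8736 ± 733 in WT (SD, n = 2). Near Trmt61a on chromosome 12, Ckb, 5767 bp away, stood at 409 ± 6.51 in cKO and 1136 ± 129 in WT at 48 h (SD, n = 2), and Gm36635, 19180 bp away, was listed at 0 in the cKO and at 35.1 ± 22.7 in WT at 6 h. Whether these follow from the knockout allele or the strain background was not tested.

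Within anticodon families, most tRNA genes that were minor at 0 h stood higher by 48 h relative to the gene dominant at 0 h. Families were ordered on 0 h replicate 1, and genes below 20% of the dominant gene counted as minor. Over 92 minor genes of 39 families the median log2 change of their ratio to the dominant gene was 0.77 between 0 h replicate 2 and 48 h; 71 gained, 36 by over 1, and 3 lost over 1. Between the 0 h replicates the median was -0.04 and 1 gene moved by over 1, which bears on measurement noise only. Because minor and dominant genes were both chosen at 0 h, any reshuffling within families would raise this ratio. An ordering on 48 h was not run. The filter, a mean RPM of at least 10 over all 8 libraries, can also admit genes through a later rise. Val-AAC-4, for example, stood at 7.32 RPM at 0 h and 26.3 at 48 h. Cys-GCA-1 went from 194 ± 4.13 to 1468 ± 252 RPM (SD, n = 2) and Ala-AGC-3 from 34.5 ± 1.22 to 314 ± 16.4. Greater use of minor tRNA genes is a hypothesis that may explain this; reads assigned to the wrong copy, or modification left after AlkB treatment, were not tested and stay open.

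The question was whether isoacceptors that lost more m1A in the cKO changed more in activated WT cells. Over 44 isoacceptors, which are not independent replicates, Spearman's rho between the m1A loss and the log2 change was -0.0775 at 6 h (permutation p = 0.616) and -0.0692 at 48 h (permutation p = 0.652, adjusted p = 0.652 for both). Pearson's r was -0.0510 (permutation p = 0.740) and -0.0217 (permutation p = 0.880), and without iMet-CAT and Ala-AGC, the isoacceptors farthest from the median loss, -0.110 and -0.0985. No relation was detected. Both rho lay under the bound of 0.15 set beforehand, but by less than their permutation SDs of 0.151 and 0.153, a condition applied after the values were seen, so a weak relation cannot be told apart from none.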
